A study of Danio rerio with 12 samples.

How the data were processed

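Single-cell libraries of 2 sorts of cells, macrophages and lateral line cells, were analysed in 6 groups each, with 1 library per group. Median depth and cell numbers per library are given with the results, and the precision they allow is given as counting intervals. The values started from were UMI counts per gene and cell. Per the submitters' processing notes, the authors mapped the reads to the zebrafish genome danRer11 with Cell Ranger and deposited its filtered matrices of counts, which hold called cells only. The Cell Ranger version and the gene annotation were not given in the sources used here. Per the labels' protocols, larvae were dissociated with trypsin, live nucleated cells were sorted by flow cytometry, and libraries were made with the Chromium 3′ v3.1 chemistry. No normalized values of the authors were used. Gene symbols were taken from the files, whose 32520 gene rows shared between libraries include 1309 that carry a symbol also borne by another row. Such rows were summed under the symbol for marker scores and class totals and stayed separate for clustering. Rows for the transgenes mCherry and EGFP were found in 5 libraries of the macrophage sort and were used only for the transgene counts.

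A barcode was kept when it had at least 500 genes with a UMI, at most 20% of UMIs from mitochondrial genes, and was not called a doublet. Doublets were scored per library by a Scrublet-type method, in which simulated doublets are set among the real cells. The usual automatic limit called 0 to 2.27% of barcodes, and under 0.5% in 7 libraries. A fixed rate of 0.8% per 1000 barcodes was therefore used, a choice made after those results were seen, and it called 6.69 to 10.3% per library, 9892 barcodes in all. The 6 libraries of a sort were clustered together without batch correction. Counts were scaled to 10000 per cell and log-transformed, 2000 variable genes and 30 principal components were taken, and cells were linked to 15 neighbours and clustered by the Leiden method at resolution 1. That gave 41 clusters in the macrophage sort and 42 in the lateral line sort.

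Each cluster was scored for 24 marker lists fixed before the data were examined and named after the list with the highest score. A marker counted as detected when at least 50% of the cluster's cells had a UMI. A cluster kept its name when the score was above 0, at least 3 markers and 12.5% of the list were detected, and its 10 leading genes held no more markers of another class than of its own. Clusters much shallower than their libraries and without a marker of their own among the leading genes stayed unnamed. Microglia were counted as macrophages, and lists for mantle cells, proliferating cells and haematopoietic progenitors were not used as names, nor were those for microglia, metaphocytes and dendritic cells in the lateral line sort. These conditions were settled after clusters had been seen, and 33 clusters of the macrophage sort and 32 of the lateral line sort were named. A lower detection limit was tried before and dropped. Across 4 versions of the rule the hair cell and macrophage shares were identical. The share of neuromast support cells was not: with 25% of the list required only 1 cluster kept the name, 4.19% of untreated cells and 13.8% in neomycin+0h. With no such share required 7 clusters did, 34.6% and 50.4% of cells, and with a least score of 0.25 there were 5, 33.3% and 49.1%. The version used had 6 clusters. Cells of unnamed clusters stayed in the denominators and in no class.

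Expression of a class was the sum of its UMIs in a library, given as CPM, scaled to the total of all genes in the class. A comparison divided the CPM of 2 libraries, with the exact conditional binomial (Clopper-Pearson) interval for a ratio of Poisson counts. A gene was used when either library had at least 100 summed UMIs. A count of 0 was set to 3 counts for the ratio, and such genes are given as UMI counts. A count of 1 was kept, so a gene with no UMI could rank behind a gene with 1 and be missing from the lowest genes named. Shares of cells have exact Clopper-Pearson intervals at 95%. There were 19 comparisons: 7 each in macrophages and support cells, and 5 in hair cells. With 1 library per group no test, p-value or count of changed genes was made.

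Gene lists, 23 in all, were fixed at the same time. Each list has the median log2 ratio of its measured members, an interval from 1000 Poisson resamples of the counts, and the percentile of that median among 10000 random lists of the same size matched on mean expression. A member was called higher or lower at 1.5-fold with an interval that excludes no difference. Named genes followed a fixed rule: the 5 highest and 5 lowest log2 ratios against untreated, the 8 and 8 between neomycin and MTZ, and of each list the 2 highest and 2 lowest members. Mitochondrial, ribosomal protein, haemoglobin and transgene rows and genes with placeholder names were left out. The rule was written for macrophages and support cells and was applied to hair cells unchanged. A gene that the rule picks in 1 comparison is not reported here.

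Transcripts of 2 cell types in 1 cell were counted in cells thinned at random to 2000 UMIs, with a separate draw for each set of transcripts, and shallower cells were left out (1015 in the untreated macrophage sort, 659 to 1247 in the treated libraries). At least 5 UMIs had to come from 12 hair cell markers. The macrophage condition was 25% of the median macrophage marker count of macrophages in the same library. These limits, and the 5 chemosensory genes counted the same way, were chosen after the data were seen.

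The ratios and list medians were tested on simulated counts made from the means and depths of MTZ+0h against untreated. In macrophages (12403 genes), support cells (11727) and hair cells (11056), 95.9 to 100% of genes simulated with a 2-fold or 4-fold difference were called. Their intervals held the true value for 90.0 to 100% of genes, and 0.0246%, 0.0520% and 1.11% of unchanged genes were called. Both simulated libraries were Poisson counts drawn from the untreated profile. They held no variation between libraries, dissociations or mixes of clusters, so these rates check the calculation and are not error rates for the real libraries.

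Alternatives set before the data were examined were a stricter filter (1000 genes, 10% mitochondrial UMIs), a looser one (200 genes, no mitochondrial limit), doublets kept, Leiden resolutions 0.5 and 2, a gate on marker UMIs of each cell, median-of-ratios scaling, equal weight for each cell, cells thinned to a fixed depth, and genes with 30 UMIs. The gate was redefined once after a first version named few macrophages. A wider set of clusters, named without the checks on leading genes and depth, was added after the data were seen. So were list medians within single clusters, for clusters with at least 50 cells in both libraries and genes with 30 UMIs, and counts of hsp70 UMIs in each erythroid cluster. The tools were Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-image 0.26.0, igraph 0.11.9, leidenalg 0.10.2 and matplotlib 3.10.9. Reads were not analysed here, nor was removal of free RNA from the counts attempted.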

Results

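The data were droplet-based single-cell transcriptomes of transgenic zebrafish larvae whose lateral line hair cells had been killed in different ways. The larvae carried EGFP under the macrophage promoter mpeg1, an mCherry-tagged nitroreductase under the hair cell promoter myo6b, and a nuclear mCherry reporter of the lateral line. Nitroreductase turns metronidazole (MTZ) into a toxin inside the cells that make it, and neomycin is an aminoglycoside antibiotic that enters hair cells. Cells were sorted either for the macrophage reporter (macrophage sort) or for the lateral line reporter (lateral line sort). Each sort had 6 groups: untreated, MTZ-1h, MTZ+0h, MTZ+1h, neomycin+0h and neomycin+1h. The labels do not say what MTZ-1h counts from, so it was kept as a group of its own.

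Each of the 12 libraries was the only 1 of its group, made from 600 larvae, so no difference below had a replicate check. All intervals are 95% intervals that cover counting error only. Total counts were 95831179 to 134904119 UMIs per library in the macrophage sort and 54015932 to 104924492 in the lateral line sort. The files held 124251 barcodes, of which 96077 were kept, 50016 in the macrophage sort and 46061 in the lateral line sort. The kept cells had median depths of 7830 to 10763 UMIs per library in the macrophage sort and 5181 to 5900 UMIs in the lateral line sort. Cells were named from marker genes of the clusters they fell in, so "macrophages" below are macrophage-like cells. Gene values are log2 ratios of CPM, counts scaled to the total of the class, treated over untreated unless another pair is named. A list member was called higher or lower when it differed at least 1.5-fold and its interval excluded no difference. In the paragraphs on hair cells, support cells and macrophages, each list median printed with an interval lay below the 2.5 or above the 97.5 percentile of 10000 random lists matched on size and expression, which describes these libraries and is no test of the treatment. Medians without an interval include lists that did not stand apart in this way.

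The first question was how many hair cells were left. In the untreated lateral line sort, hair cells made up 19.1% of the cells (18.3 to 20%, exact Clopper-Pearson interval, 1630 of 8527 cells). Every treated library had a smaller hair cell share: 14.6% in MTZ-1h, 8.44% in MTZ+0h and 3.08% (2.69 to 3.51%) in MTZ+1h. Neomycin left 6.44% (5.91 to 7.01%) at +0h and 7.79% (7.22 to 8.38%) at +1h. Thus the hair cell share was lowest in MTZ+1h, while the neomycin libraries differed little between their times. Support cells, the neuromast cells that surround hair cells and can replace them, made up 34.3% of the untreated lateral line sort. Their share was 43.7%, 46.6% and 58.8% in MTZ-1h, MTZ+0h and MTZ+1h, and 50.2% and 39.2% after neomycin. Clusters 6, 7, 12 and 40 scored as support cells but stayed without a name, and held 4.81% of untreated cells, 17.4% in MTZ-1h and 7.84 to 13.3% elsewhere. When 25% of the marker list was required, the support cell share was 4.19% untreated, 10.0%, 9.49% and 9.25% in MTZ-1h, MTZ+0h and MTZ+1h, and 13.8% and 7.36% after neomycin, so MTZ+1h was no longer the highest. Shares are relative, so a lower share of 1 class raises the others.

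Other cells of the lateral line sort also differed. Ionocytes made up 4.87% of untreated cells and at most 2.09% of any treated library. Epidermis was 10.1% when untreated and 3.72 to 6.5% in treated libraries. Erythroid cells ran the other way in the lateral line sort, from 1.62% untreated to 6.08% in neomycin+0h and 6.38% in neomycin+1h. Cells that carried macrophage markers were rare in the lateral line sort, 0.188% (0.107 to 0.305%) when untreated and 1.24% (1.00 to 1.51%) in neomycin+0h. Between 11.9% and 21.6% of cells in a lateral line sort library fell in clusters without a name.

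**Figure D1:**
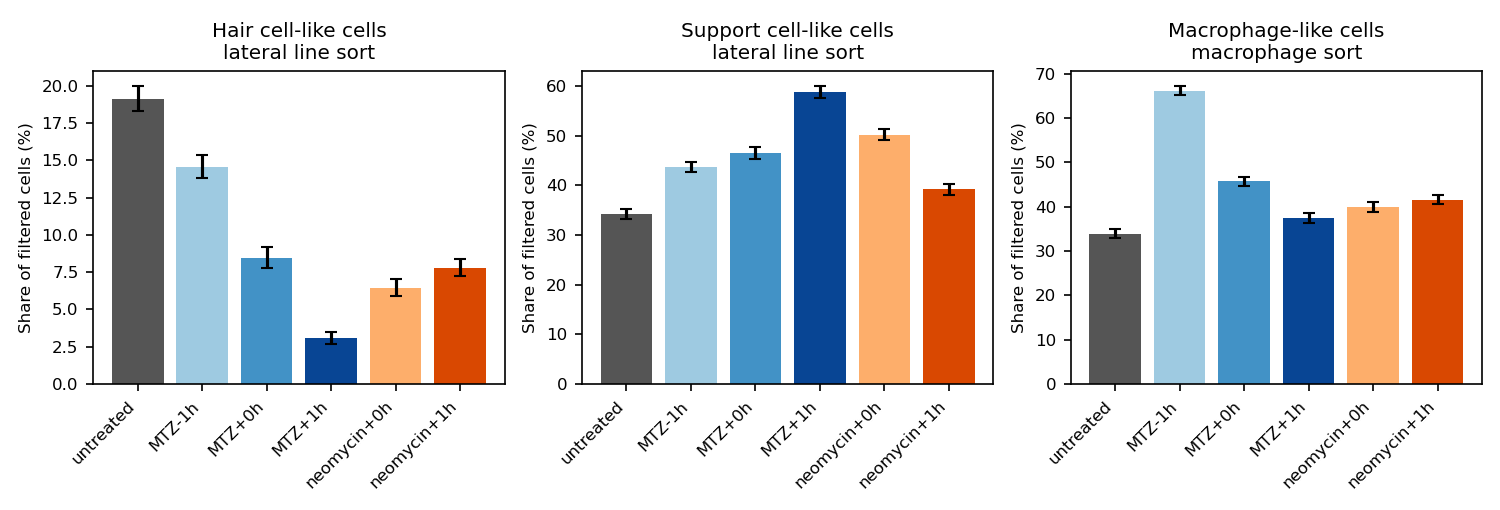
Share of kept cells (percent, exact 95% intervals) named as each class in each library of the lateral line sort and of the macrophage sort. Hair cells were 19.1% of untreated lateral line sort cells and 3.08% in MTZ+1h.

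The hair cells that remained after MTZ differed from untreated ones first in their heat shock genes. In MTZ-1h hair cells the heat shock and protein folding list had a median log2 ratio of 3.18 (3.05 to 3.2), with 21 of 25 members higher and none lower. The inducible chaperones hsp70.3 and hsp70.2 were at 9.10 (8.81 to 9.40) and 7.66 (7.43 to 7.91), while the constitutive chaperones hsp90ab1 (−0.14) and hspa8 (0.17) stayed close to untreated. The oxidative stress and iron list had a median of 0.64 with 19 of 35 members higher and 9 lower. It was led by ncf4 (5.46), a subunit of the phagocyte NADPH oxidase, and slc40a1 (4.87 (4.81 to 4.94)), the iron exporter ferroportin. Its lowest members were nfe2l2a (−1.25), the antioxidant regulator Nrf2, and gstp1 (−1.13).

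MTZ-1h hair cells also had lower calcium and ion transport genes. In that list of hair cell genes, 14 of 22 members were lower and 3 higher, with a median of −0.81 (−0.83 to −0.71). The vesicular glutamate transporter gene slc17a8 was at −3.28 and calm3a, a calmodulin gene, at −2.01, against 2.71 for the calcium pump gene atp2a2a and 2.07 for the calcium buffer gene pvalb9. Immediate early genes, transcription factors switched on within minutes of a stimulus, had a median of 1.32, with 28 of 37 members higher, fosl1a (5.91) and dusp5 (5.67) most. The unfolded protein and integrated stress response list (0.64) had 18 of 34 members higher, trib3 (4.36) and sesn2 (3.88) most. Glycolysis and hypoxia (0.79), p53 and apoptosis (0.31) and Notch (0.39) also lay above 97.5% of matched random lists. The cell cycle list was at 0.95 but 1.54 with a stricter cell filter and 0.45 with each cell thinned to a fixed depth. Among the 5 highest genes were il2rga (8.04 (6.17 to 11)), a cytokine receptor chain, zte38 (8.39) and the erythroid marker slc4a1a (9.23 (7.67 to 11.51)). Among the 5 lowest were pdia2 (−5.70 (−11.01 to −3.19)), dclk3 (−4.80), rprma (−4.39) and the macrophage marker mrc1a (−4.82). The lowest also held enam, with no UMI in MTZ-1h and 156 when untreated. Over all genes the median was −0.21, and the interferon response list (−0.61) was not apart from matched random lists.

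MTZ+0h hair cells kept the heat shock profile. The list median was 3.19 (3.04 to 3.25), with 20 of 24 members higher, hsp70.3 at 8.65 and hsp70.2 at 7.53. Calcium and ion transport genes were again lower (−0.79, 12 of 22 members), with the calcium-binding protein gene s100s at −2.69 and slc17a8 at −2.59. Hair cell specification genes had a median of 0.51 (0.26 to 0.66) with 14 of 30 members higher and 8 lower. The transcription factor genes sox4a (2.57) and insm1b (2.1), which act early in hair cell formation, were the highest, and foxg1a (−2.3) and barhl1a (−1.97) the lowest. JAK-STAT3 signalling (0.82) was led by cish (1.62) and stat3 (1.61). The stress response list (0.68) was led by sesn2 (4.18) and the amino acid transporter gene slc7a5 (3.91), and the immediate early list (0.58) by fosl1a (5.74) and atf3 (4.21). Outside the lists, zte38 (7.87), the erythroid marker slc4a1a (8.55 (6.98 to 10.84)) and pyyb, a gut peptide gene with 2216 UMIs against none when untreated, were highest. The lowest were rprma (−4.87) and enam (−4.72 (−10.04 to −2.22)), with markers of pancreas (ela2, −4.99 (−8.04 to −3.13)), epidermis (krt92, −4.89 (−10.20 to −2.39)) and macrophages (mrc1a, −4.88 (−7.17 to −3.33)).

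In MTZ+1h hair cells the same chaperones were higher by less. The heat shock list was at 1.68 (1.54 to 1.83) with 20 of 24 members higher, hsp70.3 at 7.31, hsp70.2 at 5.53 and hsp70.1 at 5.04. The ferritin gene fthl29 (5.48) was also among the 5 highest, next to the muscle marker pvalb2, which had 101 UMIs against none. Hair cell specification genes were at 0.45, with sox4a (2.87) and insm1b (2.76) highest and sox11a (−1.79) and prox1a (−1.51) lowest. Calcium and ion transport genes were at −0.52 with 10 of 22 lower, pvalb9 (−2.84) and the mechanotransduction channel gene tmc2a (−1.36) most. The stress response list was at 0.60, with sesn2 at 2.07 and creld2 at 1.52, and at 1.04 when cells were thinned to a fixed depth. Immediate early genes, unlike in the other libraries, had a median of −0.24. The lowest genes were mst1 (−5.17 (−10.48 to −2.68)), enam (−4.66 (−9.98 to −2.16)), rxfp2l (−4.46 (−9.78 to −1.96)), pdia2 (−4.28 (−9.60 to −1.78)) and the neutrophil marker lyz (−4.24 (−9.55 to −1.73)). This library held 221 hair cells, so its intervals were wider.

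The mix of hair cell clusters differed as well. Of untreated hair cells 84.2% lay in cluster 5, and none lay in cluster 8, whose leading genes were hsp70.3 and hsp70.2. Cluster 8 held 93.7% of MTZ-1h, 81.3% of MTZ+0h and 47.1% of MTZ+1h hair cells, and none of the neomycin hair cells. Cluster 16, marked by the early hair cell gene atoh1b, held 14.5% of untreated hair cells, 39.0% in neomycin+0h and 34.8% in neomycin+1h. In MTZ-1h, MTZ+0h and MTZ+1h it held 1.40%, 2.27% and 15.8% of them.

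Hair cells after neomycin had no such heat shock profile. In neomycin+0h the heat shock list was at 0.09 and the immediate early list at 2.82 (2.64 to 3.01), with 34 of 39 members higher and 1 lower. The transcription factor genes egr2a (6.96 (6.14 to 7.92)), cebpb (6.54 (6.12 to 6.98)), egr3 (6.43 (5.18 to 8.07)) and junba (6.19) were among the 5 highest genes of all. JAK-STAT3 signalling was at 1.24 (1.18 to 1.39) with 9 of 14 members higher, led by its feedback inhibitors socs3a (4.35) and socs3b (3.61), with the receptor gene lepr (−1.11) lowest. NF-kB targets were at 0.48, with irf1b (2.59) and tnfaip3 (1.66) highest. Hair cell specification genes were at 0.88 with 18 of 30 members higher, led by gadd45ga (3.19) and insm1b (2.40), while barhl1a was at −1.63. That list was at 0.34 when called doublets were kept, and it was not separated from the larger share of cluster 16 in this library. Calcium and ion transport genes, lower after MTZ, were at 0.08, with pvalb9 (2.92), a leading gene of cluster 37, highest and s100s (−1.89) lowest. The fifth of the highest genes was dusp2 (6.10), also a lymphoid marker. The lowest were the pancreatic genes prss59.2 (−4.60), cela1.6 (−4.29) and sycn.2 (−4.21 (−7.28 to −2.32)), then c6ast4 (−5.71 (−11.03 to −3.21)) and enam (no UMI, 156 when untreated).

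In neomycin+1h hair cells the immediate early median was 0.86 (0.79 to 1.02), with fosl1a (5.69) and cebpb (5.66) highest. JAK-STAT3 signalling stayed at 1.16 (1.09 to 1.24), led by socs3b (3.13) and socs3a (2.41), though at 0.72 when genes with 30 UMIs were counted. The Notch list was at 0.58, with 14 of 29 members higher and the Notch target her4.1 at 2.2. Hair cell specification genes were at 0.59, led by gadd45ga (3.14) and sox4a (2.66), and at 0.16 when called doublets were kept. Matrix remodelling and wound response (0.72) and glycolysis and hypoxia (0.55) were led by igfbp1a (3.84) and the lactate exporter gene slc16a3 (2.92). The cell cycle list was at 0.80 (0.30 when called doublets were kept). The highest genes outside the lists included lin28a (6.06 (5.97 to 6.15)), an RNA-binding protein gene of stem cells, and adam8b (6.28 (5.59 to 7.07)), a metalloproteinase. The muscle markers actc1b (6.07 (4.81 to 7.71)) and pvalb2 (112 UMIs against none) were next to them. The lowest were enam (no UMI), the neuronal marker elavl3 (−3.91), the macrophage marker mrc1a (−3.81), the blood progenitor marker gata2b (−3.22) and pdia2 (−3.19). All genes together had a median of 0.12.

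In support cells the question was which inflammatory and regenerative genes differed after each treatment. MTZ-1h support cells had higher JAK-STAT3 genes and lower interferon and Notch genes. JAK-STAT3 signalling, which supports regeneration in several fish tissues, had a median of 0.92 (0.65 to 1.03), with 11 of 19 members higher, socs3b (2.40) and stat3 (1.78) most. The interferon response had a median of −1.34 (−1.42 to −1.08), with 12 of 16 members lower, psme2 (−2.36) and ifi46 (−2.35) most, and mxe (1.25) highest. Of the Notch list, 17 of 30 members were lower and 2 higher (median −0.63 (−0.72 to −0.56)), led by lfng (−2.11), a glycosyltransferase that tunes the receptor, and the target her15.2 (−1.98). Glycolysis and hypoxia genes had a median of 0.96 (0.90 to 1.07), with 18 of 26 members higher, pfkfb3 (2.22) and pfkpa (1.76) most.

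Heat shock genes of MTZ-1h support cells had a median of 0.52, with hsp70l at 7.48 (4.99 to 12.79) and hsp70.3 at 4.75. The immediate early list (0.55) split, with egr2a (4.87) and egr3 (4.44) highest and klf2a (−3.70) and csrnp1a (−2.2) lowest. Antigen presentation was at −0.93, with tap1 at −2.07. Matrix and wound genes (0.37) were led by igfbp1a (4.46) and timp2b (3.38). Wnt (0.32) and stress response (0.28) medians were above 0 by less. Of the cytokine list, il11b (4.3), an interleukin that signals through gp130, was highest, while ccl20a.3 had no UMI in MTZ-1h against 109. That list's median of −0.60 was 0.10 in a wider set of clusters. Hair cell transcripts found in support cells, the list of calcium and ion transport, were lower (median −0.65, tmc2b −2.01 and otofb −1.79). Of support cells thinned to 2000 UMIs, 65.1% held at least 5 UMIs of hair cell markers when untreated and 28.2% in MTZ-1h, against 60.0% and 13.2% of fibroblasts in the same libraries, so background RNA was not separated from support cell expression. With clusters at resolution 2 that list's median was 0.19. The 5 highest genes were hsp70l, the muscle marker pvalb2 (7.53 (5.04 to 12.84)), the eye marker rho (5.40), and the peptide genes pyyb (7.27 (5.41 to 10.32)) and rln3a (5.54 (3.66 to 8.60)). The 5 lowest were the gut genes fabp6 (−10.14 (−15.45 to −7.66)) and gip (no UMI, 109 untreated), the macrophage marker ctsl.1 (−7.47 (−9.76 to −5.91)), epdl2 (−7.25 (−9.54 to −5.69)) and ccl20a.3. The median over all genes was −0.11.

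MTZ+0h support cells had the highest JAK-STAT3 median of the MTZ libraries, 1.00 (0.76 to 1.26), with an interval that overlapped that of MTZ-1h. Of the list's 18 members 11 were higher, the feedback genes socs3b (3.31 (3.17 to 3.44)) and socs2 (2.12) most, and bcl6aa (−2.04) was lowest. The unfolded protein and integrated stress response was at 0.72 (0.65 to 0.80) with 21 of 37 members higher and 1 lower, led by manf (1.76) and creld2 (1.71), both factors of the endoplasmic reticulum. The interleukin gene il11b (4.96) and the neutrophil attractant cxcl8a (3.07) led the cytokine list, in which 6 of 12 members were lower (ccl20a.3, −3.74 (−4.90 to −2.76)). Its median of −0.67 was 0.19 with genes of 30 UMIs. Notch genes were at −0.75 with 18 of 30 members lower, her15.2 (−2.75) and her9 (−2.08) most. The Fgf list was at −0.29, with fgfbp2a (−2.73) and the ligand fgf3 (−2.61) lowest. Interferon (−0.74) and antigen presentation (−1.01) genes were lower, psme2 (−2.50) and tap1 (−2.16) among them, and heat shock (0.71) and glycolysis (0.55) genes higher. Of the immediate early genes (0.58), 19 were higher and 11 lower, from egr3 (3.84) and atf3 (3.16) to fosb (−2.07). The hair cell list of calcium and ion transport was at −0.72 (tmc2b −2.69), and 10.1% of these support cells held 5 UMIs of hair cell markers. The highest genes were pvalb2 (8.28 (5.80 to 13.59)) and mylpfa (6.39 (4.52 to 9.45)), both muscle markers, hsp70l (7.10 (4.60 to 12.41)), rln3a (6.17 (4.29 to 9.22)) and the transcription factor gene sall1b (5.01). The lowest were fabp6 and the neutrophil marker lyz, with no UMI against 791 and 150, then ctsl.1 (−7.68 (−10.73 to −5.81)), gip (−6.91 (−12.22 to −4.4)) and epdl2 (−5.87).

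In MTZ+1h support cells the Fgf pathway stood lowest under the settings used, at −0.72 (−0.85 to −0.57). Of its 23 members 12 were lower and 1 higher, with fgf3 (−2.70) and the pathway's feedback gene spry4 (−2.46) most. Wnt genes were at −0.31, with the inhibitors dkk2 (−2.15) and notum1a (−1.29) lowest, and Notch genes at −0.56, with her4.1 (−1.76) and hey1 (−1.58) lowest. JAK-STAT3 signalling was still at 0.65, led by socs3b (2.71) and socs1a (2.25), and the stress response at 0.53, led by manf (1.60) and ddit4 (1.54). Heat shock genes were at 0.46 (hsp70.3 3.36), glycolysis genes at 0.41 and interferon genes at −0.61 (psme1 −1.42). The interferon median lay lower than that in some other settings. The immediate early list was at −0.01, with 8 members higher and 14 lower, fosaa at −3.41 and klf4 at −2.75. Antigen presentation was at −0.57 and the hair cell list of calcium and ion transport at −0.57 (tmc2b −3.45), with 9.57% of support cells holding 5 UMIs of hair cell markers. The hormone synthesis gene star (9.92 (7.44 to 15.23)) of the interrenal gland was highest, followed by pvalb2 (9.91 (7.43 to 15.22)) and mylpfa (7.25 (5.39 to 10.30)) of muscle, rln3a (6.86 (5.00 to 9.91)) and c7b (6.57 (4.08 to 11.88)). Lowest were fabp6 and gip (no UMI, 791 and 109 untreated), epdl2 (−6.57), lgals2b (−4.66) and ctsl.1 (−4.14).

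Neomycin+0h support cells were set apart by immediate early genes. The list median was 2.66 (2.59 to 2.74), with 34 of 40 members higher and 1 lower, led by egr2b (6.80 (5.76 to 8.12)) and egr2a (6.47 (6.21 to 6.75)), with klf2a (−1.62) lowest. JAK-STAT3 signalling was at 1.48 (1.31 to 1.53) with 14 of 19 members higher, socs1a (4.31) and socs3b (4.1) most. The p53 and apoptosis list was at 0.76, with the growth arrest genes gadd45bb (3.49) and gadd45ba (2.32) highest and mdm2 (−0.63) lowest. NF-kB targets were at 0.33, led by bcl3 (3.16) and the cyclooxygenase gene ptgs2a (2.55). The interferon list was at 0.36, unlike in the MTZ libraries, with mxe (3.02) highest. In the cytokine list (0.12) il11a (5.30) was highest. Glycolysis and hypoxia (0.57) was led by pfkfb3 (3.95) and the glucose transporter gene slc2a1b (3.38).

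Notch genes of neomycin+0h support cells were at −0.75 (−0.50 after median-of-ratios scaling), with 18 of 30 lower, the ligand dld (−2.66) and the target hey2 (−2.28) most. Hair cell specification genes were at −0.47, with dld and the progenitor factor sox2 (−1.78) lowest, and Wnt genes at −0.45, with wnt10a at −1.21. The hair cell list of calcium and ion transport was at −0.56 (s100s −2.32), and 24.3% of support cells held 5 UMIs of hair cell markers. Other genes at the top were pvalb2 (7.26 (4.76 to 12.57)), hsp70l (6.64 (4.14 to 11.95)) and tcap (6.37), a muscle gene. At the bottom were fabp6 and gip (no UMI), epdl2 (−6.41), ctsl.1 (−6.41) and aqp10a (−4.72). Over all genes the median was −0.28, the largest shift of any comparison.

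Neomycin+1h support cells had the lowest Notch median, −1.24 (−1.3 to −1.17), and lay at −1.35 to −0.15 within single clusters. Of 30 members 23 were lower and 1 higher, with hey2 (−2.80) and her15.2 (−2.45) lowest and numb (1.42), an inhibitor of Notch, highest. Fgf genes were at −0.46, with fgf3 (−2.52) and fgfbp2a (−2.32) lowest. Glycolysis and hypoxia genes were at 0.75 (0.64 to 0.79), led by slc16a3 (3.27) and pfkfb3 (3.05), and JAK-STAT3 genes at 0.44, led by the interleukin 11 receptor gene il11ra (2.32) and socs3b (2.2). In the cytokine list il11b (5.56) and cxcl8a (2.89) were highest, and ccl19a.1 (−2.71) lowest. That list's median of −0.84 was 0.08 with a stricter cell filter and 0.22 in a wider set of clusters. The immediate early list was at −0.05 and the interferon list at −0.41. The hair cell list of calcium and ion transport was at −0.57 (tmc2b −2.67), and 12.4% of support cells held 5 UMIs of hair cell markers. The 5 highest genes were pvalb2 (8.38 (5.90 to 13.69)), rln3a (8.16 (6.30 to 11.21)), the complement gene c7b (7.81 (5.33 to 13.12)), the hormone gene pomcb (6.73 (4.23 to 12.04)) and fosl1b (6.65 (4.15 to 11.96)). The lowest were ctsl.1 (−9.07 (−14.38 to −6.58)), fabp6 and gip (no UMI), epdl2 (−6.04) and nlgn4xa (−5.13).

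Set directly against MTZ+0h, neomycin+0h support cells had higher immediate early and interferon genes and lower chaperone genes. The immediate early median was 2.23 (2.13 to 2.26), with 36 of 40 members higher and none lower, fosb (6.13 (5.90 to 6.36)) and nr4a3 (5.75 (5.56 to 5.94)) most. Interferon genes were at 1.86 (1.67 to 1.99), with 15 of 20 members higher, gbp1 (3.01) and isg15 (2.82) most, and antigen presentation genes at 1.36 (tap1 2.51). Heat shock genes were at −0.94, with serpinh1b (−2.86) and hsp70.3 (−2.77) lowest. The stress response was at −0.66, with herpud1 (−2.13) and creld2 (−1.98) lowest and chac1 (2.39) highest, and at −0.39 after median-of-ratios scaling. JAK-STAT3 (0.86) and p53 (0.54) genes were higher, socs1a (2.62) and pmaip1 (2.58) among them. Hair cell specification genes were at −0.62 (−0.36 after that scaling), sox4a (−2.85 (−3.01 to −2.70)) and dld (−1.77) lowest. Among the 8 highest genes were nr4a1 (4.25), jdp2b (4.31), egr2b (5.58), dusp2 (4.55), tcap (4.32) and the light-responsive clock gene per2 (4.38 (4.21 to 4.55)). The 8 lowest included noxa1 (−4.02), pir (−3.39), iqsec2a (−3.11), cxcl8a (−3.09), ptgdsb.2 (−2.98) and efr3ba (−2.94). All genes together had a median of −0.22.

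Neomycin+1h support cells, set against MTZ+1h, had lower Notch genes, with some wound genes higher and some cell cycle genes lower. Matrix remodelling and wound response was at 0.27 (0.21 to 0.36) with 10 of 38 members higher, the fibronectin receptor chain itga5 (3.26) and s100w (2.52) most. Notch genes were at −0.69 (−0.74 to −0.64), with 18 of 30 lower, hes6 (−1.56) and the receptor notch1a (−1.49) most. Cell cycle genes were at −0.54, with the nucleotide reductase gene rrm2 (−1.58) and birc5a (−1.37) lowest. In the cytokine list il11b (2.67) and cxcl8a (1.46) were highest and il15 (−2.01) lowest. Its median of −0.96 did not hold, being −0.11 with a stricter cell filter and 0.22 in a wider set of clusters. NF-kB targets (0.29), Fgf (0.23) and glycolysis (0.27) genes lay above 0, led by ptgs2b (2.65), dusp4 (1.78) and slc16a3 (3.4), and pyroptosis genes (−0.51) below it. The light-responsive gene per2 (4.51 (4.34 to 4.68)) was again among the 8 highest. The others were cry5 (4.24 (3.91 to 4.59)), also light-responsive, eevs (5.21), loxl2a (4.65), trib1 (4.09), wdr76 (3.91), lin28a (3.91) and cyp27c1 (3.61). Of the 8 lowest, 5 were genes of the interrenal steroid pathway: star (−9.45 (−12.50 to −7.60)), cyp11c1 (−4.89 (−7.19 to −3.31)), cyp11a2 (−4.68), fdx1b (−4.99) and cyp21a2 (no UMI against 192). The others were hsp70.3 (−4.81) and the somatostatin genes sst1.1 (−6.26) and sst1.2 (−5.22). The median over all genes was −0.16.

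Support cells lay in different clusters by library. Cluster 1 held 48.5% of untreated support cells and 16.5 to 29.2% of treated ones, cluster 0 held 16% against 26.6 to 40.7%, and cluster 15 held 10.3% against 0.309 to 6.25%. Medians within single clusters were therefore computed after the other results had been seen. They used genes with 30 UMIs. The Notch list ran from −0.77 to 0.10 in MTZ-1h, −1.06 to −0.12 in MTZ+0h, −0.69 to 0.00 in MTZ+1h and −1.02 to −0.23 in neomycin+0h. The interferon list ran from −1.58 to −0.29 in MTZ-1h and 0.09 to 0.87 in neomycin+0h, but had both signs in MTZ+0h (−1.93 to 0.08), MTZ+1h (−0.84 to 0.39) and neomycin+1h (−0.91 to 0.69). The Fgf list lay below 0 within each cluster in MTZ+1h (−0.99 to −0.07) and neomycin+1h (−1.05 to −0.12). It had both signs in MTZ-1h (−0.34 to 0.25), MTZ+0h (−0.32 to 0.31) and neomycin+0h (−0.65 to 0.10). JAK-STAT3 genes ran from 0.14 to 1.08 in MTZ-1h, 0.14 to 1.53 in MTZ+0h, −0.01 to 0.94 in MTZ+1h, 0.84 to 1.75 in neomycin+0h and 0.18 to 1.33 in neomycin+1h. A class median thus also carried the mix of clusters.

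**Figure D2:**
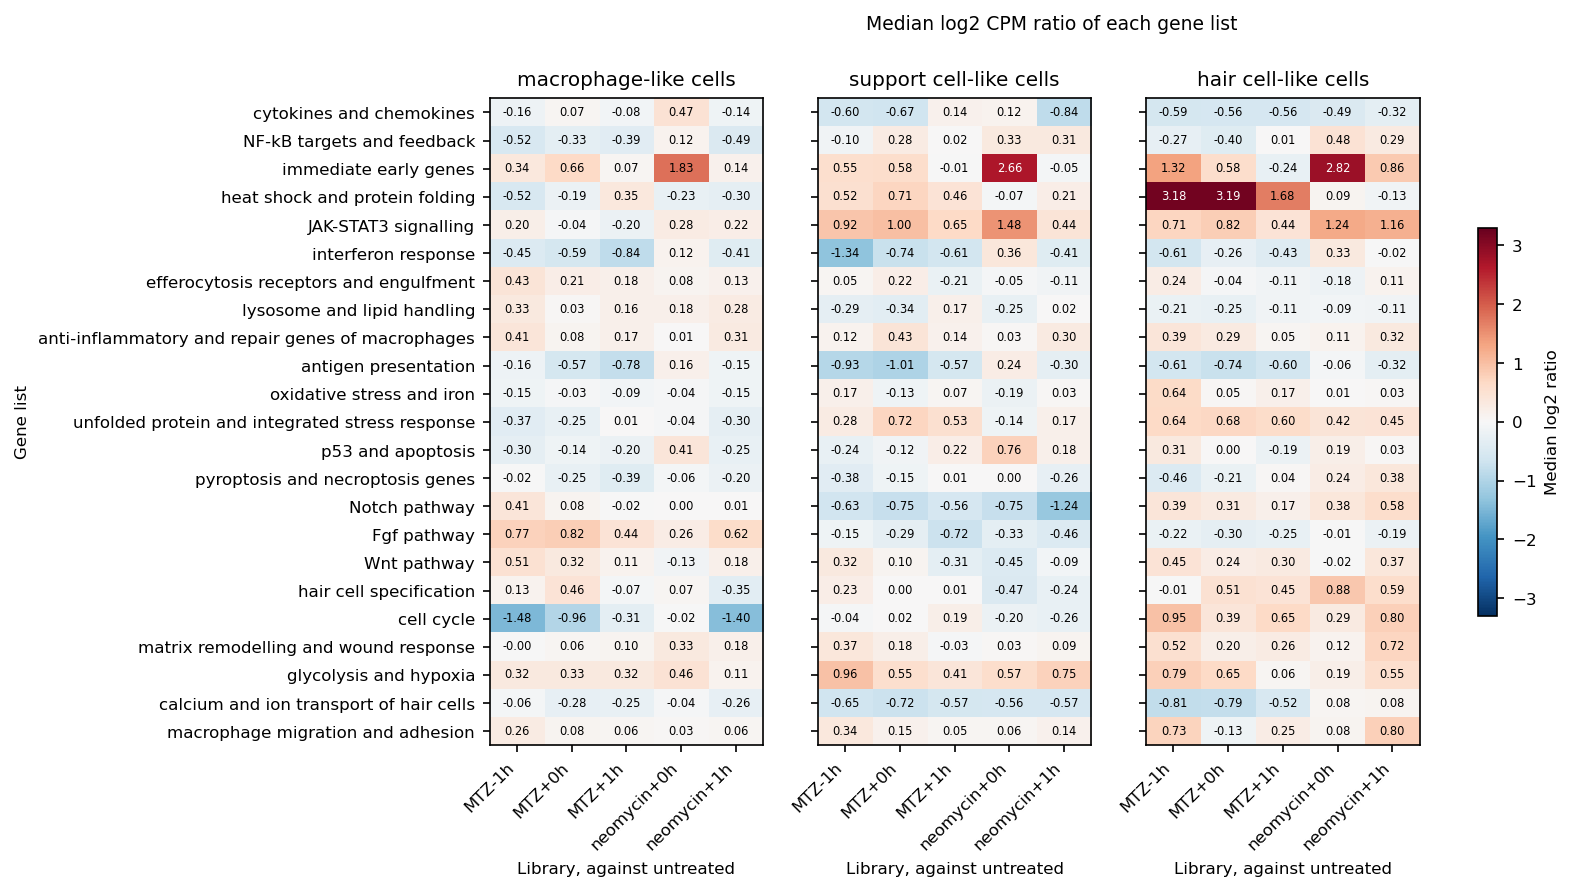
Heat map of the median log2 CPM ratio of each gene list in macrophages, support cells and hair cells, per treated library against untreated. The median is printed in each field, without intervals. In neomycin+0h, immediate early genes lay at 1.83 in macrophages, 2.66 in support cells and 2.82 in hair cells. Heat shock genes lay at 3.18 in MTZ-1h hair cells.

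The macrophage sort held more than macrophages. In the untreated library 33.9% of cells (32.9 to 34.9%) were macrophages, and the macrophage share of the treated libraries was 66.2% in MTZ-1h, 45.7% in MTZ+0h, 37.4% in MTZ+1h, 40.0% in neomycin+0h and 41.6% in neomycin+1h. The untreated share was 18.7% with called doublets kept and 17.9% with clusters at resolution 2, and the neomycin+0h share 26.5% with called doublets kept. With a gate on marker UMIs the macrophage share was 30.5% untreated, 51.7% in MTZ-1h, 30.6% in MTZ+0h and 28.2% in MTZ+1h, so MTZ+0h was level with untreated and MTZ+1h below it. The untreated library also lost the most barcodes to the mitochondrial limit: 10944 passed the gene limit and 9743 both, while in MTZ-1h, next in loss, 9353 and 8918 did. Neutrophils made up 17.5% of the untreated macrophage sort and 2.77% in MTZ-1h, against 13.7 to 20% elsewhere. Metaphocytes, skin cells that resemble macrophages, made up 5.31 to 7.21% of each library of the macrophage sort. Lymphoid cells made up 3.54 to 6.38%, and 6.56 to 13.9% lay in clusters without a name. Liver or gut cells made up 2.86% of the untreated macrophage sort and 0.244 to 0.924% of treated libraries. Background RNA from such cells was not separated from macrophage expression.

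Within the macrophage class, clusters 4 and 7 held 26.8% and 38.3% of untreated macrophages. The same clusters held 35% and 24.9% of neomycin+0h macrophages, and 7.05 to 15.4% and 1.48 to 3.87% in the other libraries. Clusters 1, 2 and 3 held 9.01%, 17.3% and 5.95% of untreated and 12.8%, 15.6% and 9.99% of neomycin+0h macrophages. They held 35.6%, 19.8% and 32.8% in MTZ-1h, 26.7%, 33.2% and 26.9% in MTZ+0h, 21.8%, 29.0% and 28.0% in MTZ+1h and 27.3%, 25% and 26.8% in neomycin+1h. Cluster 11, which scored as macrophage but stayed without a name, had the interferon-induced genes cxcl11.5 and mxc among its leading genes. It held 375 untreated and 405 neomycin+0h cells, against 42 to 91 elsewhere. Within single macrophage clusters the cell cycle list ran from −1.41 to −0.59 in MTZ-1h, −1.53 to −0.47 in MTZ+0h, −1.05 to 0.23 in MTZ+1h, −0.42 to −0.03 in neomycin+0h and −1.87 to −0.73 in neomycin+1h. The interferon list lay below 0 in 5 of 6 clusters in each MTZ library, but at 0.16, 0.49 and 0.17 in cluster 4. It ran from −0.31 to 0.10 in neomycin+0h and from −0.47 to −0.03 in neomycin+1h. Other lists, such as engulfment, lysosome and repair genes, were not computed within single macrophage clusters. Their class medians below were thus not separated from the mix of clusters. Among genes named below, lrp1ab and ctsl.1 were leading genes of cluster 3, mrc1b of cluster 1, mxc of cluster 4 and apoeb of cluster 13.

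Macrophages of MTZ-1h had lower cell cycle genes, with some engulfment and lysosome genes higher. The cell cycle list was at −1.48 (−1.57 to −1.42), with 34 of 38 members lower, rrm2 (−2.46) and the thymidylate synthase gene tyms (−2.41) most, and ccnd1 (0.82) highest. Receptors for dying cells (efferocytosis) were at 0.43 (0.41 to 0.52) with 10 of 23 members higher, led by lrp1ab (2.05) and scarb1 (1.76). Lysosome and lipid genes were at 0.33 (0.28 to 0.40), led by the protease gene ctsl.1 (2.25) and the apolipoprotein gene apoeb (1.59). Anti-inflammatory and repair genes were at 0.41 with 13 of 31 members higher, the mannose receptor genes mrc1a (1.73) and mrc1b (1.46) most and arg2 (−1.61) among the lowest. NF-kB targets were at −0.52, with 11 of 23 lower, tnfaip2b (−2.23) and bcl3 (−1.76) most. The interferon list was at −0.45, with mxc (−2.96) and psmb13a (−2.05) lowest. The stress response (−0.37; psat1 −2.17), heat shock (−0.52; hsp90aa1.2 −2.34) and p53 (−0.30; fas −1.57) lists were below 0.

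Fgf (0.77), Wnt (0.51), Notch (0.41) and immediate early (0.34) lists of MTZ-1h macrophages lay above 0, with spry2 (1.72), tcf7l1b (1.17), notch3 (2.60) and egr3 (1.79) highest. So did the lists of glycolysis (0.32; ca9 2.3) and of macrophage migration and adhesion (0.26; ltb4r 1.18). The highest genes of all were kif9 (7.16 (6.23 to 8.29)), a kinesin, and nefmb (6.43 (5.68 to 7.30)), a neurofilament gene, then tmtopsb (5.98 (4.41 to 8.26)), oaz2b (5.28 (3.4 to 8.35)) and entpd3 (4.87). The lowest were plac8.1 (−8.27 (−13.58 to −5.78)), the lipid scavenger gene cd36 (−8.04 (−13.35 to −5.55)), chia.1 (−7.97 (−13.28 to −5.48)), soul2 (−7.35 (−12.67 to −4.85)) and the gut marker fabp1b.1 (−7.89). Whether these transcripts, those of cd36 and chia.1 included, came from macrophages or from background RNA was not tested.

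Cell cycle and interferon lists had medians below 0 in MTZ+0h macrophages too. The cell cycle list was at −0.96 (−1.04 to −0.84), with 24 of 39 members lower (rrm2 −1.94, ccna2 −1.83). The interferon list was at −0.59 (−0.82 to −0.57), with 16 of 31 lower and none higher (psmb13a −2.83, mxc −2.68). Antigen presentation was at −0.57, with the immunoproteasome genes psmb12 (−2.83) and psmb8a (−2.28) lowest and cd83 (1.32) highest. Immediate early genes were at 0.66 (0.63 to 0.74) with 21 of 38 higher, ier2a (2.01) and egr1 (1.86) most. Among cytokines (0.07) the neutrophil attractant cxcl8b.1 (2.43) was highest and ccl19a.1 (−5.80), a lymphoid chemokine, lowest. Efferocytosis genes were at 0.21 (lrp1ab 1.35, scarb1 1.31) and glycolysis and hypoxia genes at 0.33 (ca9 1.67, ddit4 1.42). The Fgf list was at 0.82 but at 0.38 with genes of 30 UMIs. NF-kB targets were at −0.33 (ptgs2a −2.14), and Wnt genes at 0.32 (tcf7l1b 0.77). After kif9 (7.01) and nefmb (4.91) the highest genes were ugt5a2 (3.90), hhipl1 (3.26) and penka (2.91). The lowest were ca15a (−6.72), sst1.2 (−6.69 (−9.75 to −4.81)), soul2 (−6.42 (−9.49 to −4.54)), tcnba (−5.93) and ccl19a.1.

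MTZ+1h macrophages had the lowest interferon median, −0.84 (−0.91 to −0.70). Of 31 members 18 were lower, mxc (−2.36) and psmb13a (−2.3) most, and samhd1 (0.82) was highest. Antigen presentation was at −0.78 (−0.90 to −0.68) with 10 of 17 members lower (psmb12 −1.96). NF-kB targets (−0.39; bcl3 −1.97) and pyroptosis and necroptosis genes (−0.39; the pore-former gsdmeb −1.3) were below 0, as were JAK-STAT3 (−0.20) and p53 (−0.20) genes. The cell cycle list was at −0.31, split between cenpf (−1.66) and cdc20 (−1.63) of mitosis and mcm6 (0.69) and mcm2 (0.65) of DNA replication. Heat shock genes were at 0.35 (0.28 to 0.41) with 4 of 20 members higher, hsp70.2 (1.19) most. Lysosome (0.16; ctsl.1 1.63), Fgf (0.44; spred2a 1.08) and glycolysis (0.32; ddit4 1.89) lists lay above 0, and immediate early genes at 0.07. The highest genes were kif9 (5.72), cyb561a3b (3.83), the kidney gene slc22a6l (3.43), ugt5a2 (3.35) and nefmb (3.09). The lowest were chia.2 (−8.93 (−11.97 to −7.07)), chia.1 (−7.85 (−13.16 to −5.36)) and sst1.2 (−7.50 (−12.81 to −5.00)), and the gut markers fabp1b.1 (−7.90) and fabp2 (−7.54).

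Neomycin+0h macrophages had higher immediate early genes, with some cytokine and p53 genes higher. The immediate early list was at 1.83 (1.76 to 1.93), with 35 of 40 members higher and none lower, csrnp1a (5.26 (4.90 to 5.65)) and the nuclear receptor nr4a3 (4.4 (4.21 to 4.59)) most. Cytokines were at 0.47 (0.28 to 0.54) with 12 of 30 members higher, the granulocyte growth factor csf3b (2.91) and cxcl8b.1 (2.87) most and ccl19a.1 (−3.18) lowest. The p53 and apoptosis list was at 0.41 with 15 of 34 higher, plk2b (3.43) and the death gene pmaip1 (2.27) most. Matrix genes were at 0.33 (igfbp1a 2.75, mmp9 2.25), glycolysis genes at 0.46 (ddit4 3.41) and JAK-STAT3 genes at 0.28 (osmr 1.57). Lysosome and lipid genes were at 0.18, led by the lipid droplet gene plin2 (2.25). Interferon (0.12; mxe 2.17) and cell cycle (−0.02) lists lay near 0, and heat shock genes at −0.23 (hsp70.3 −2.74). Repair genes (0.01) split between the osteopontin gene spp1 (5.28) and vegfc (−1.03), and antigen presentation (0.16) had cd83 (2.80) highest. The highest genes were clec19a (6.39 (3.88 to 11.70)), the lectin genes jac2 (5.81 (3.93 to 8.87)), jac3 (5.81 (4.24 to 8.10)) and jac9 (5.6), and rnd2 (5.44 (3.55 to 8.50)). The lowest were plac8.1 (−8.22 (−13.53 to −5.73)), tcnba (−7.81 (−13.12 to −5.31)), chia.2 (−7.19), fabp1b.1 (−8.43) and fabp2 (−6.99), the last 2 gut markers.

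Neomycin+1h macrophages had lower cell cycle genes, with some repair genes higher. The cell cycle list was at −1.40 (−1.49 to −1.36), with 35 of 38 members lower, the replication licensing genes cdt1 (−2.69) and cdc6 (−2.35) most. Repair genes were at 0.31 (0.23 to 0.39) with 11 of 29 higher, the metalloproteinase mmp9 (3.46) and mrc1a (1.38) most. Lysosome genes were at 0.28 with 9 of 49 higher and none lower (ctss2.1 1.55, abca1a 1.3). JAK-STAT3 genes were at 0.22, led by the oncostatin receptor gene osmr (1.87) and socs3b (1.63), and matrix genes at 0.18 (mmp2 2.41). NF-kB targets were at −0.49 (tnfaip2b −2.35), interferon genes at −0.41 (psmb13a −1.73) and the stress response at −0.30 (psat1 −1.27). The immediate early list, at 1.83 in neomycin+0h, was at 0.14 (csrnp1a 1.52). Fgf genes (0.62; spry4 1.71) were above 0 and heat shock genes (−0.30; hsp70.3 −3.19) below. The highest genes were clec19a (6.80 (4.3 to 12.12)), sst1.1 (5.27 (3.38 to 8.33)), nefmb (5.22), slc35g2a (4.61) and map3k15 (4.08). The lowest were the pancreatic gene amy2a (−6.25 (−8.54 to −4.68)), ca15a (−5.61), slc20a1a (−5.34), sst1.2 (−4.99) and tcnba (no UMI against 169). Over all genes the median was −0.12.

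Against MTZ+0h, neomycin+0h macrophages as a class had higher inflammatory genes of several kinds. Clusters 4 and 7 held 35% and 24.9% of neomycin+0h macrophages, against 7.05% and 2.35% of MTZ+0h ones. No ratio between these libraries was computed within single clusters, so the class medians here were not separated from the mix of clusters. Against untreated, the interferon list of cluster 4 was at 0.49 in MTZ+0h and 0.05 in neomycin+0h. In clusters 1, 2, 3 and 7 it lay lower in MTZ+0h than in neomycin+0h. Immediate early genes were at 1.07 (1.02 to 1.11) with 31 of 40 members higher, csrnp1a (5.17 (4.88 to 5.48)) and nr4a3 (2.65) most. NF-kB targets were at 0.67 (0.59 to 0.74) with 13 of 23 higher and none lower, ptgs2a (2.65) and bcl3 (1.71) most. Interferon genes were at 0.76 (0.70 to 0.90) (psmb13a 2.90, mxc 2.82), antigen presentation at 0.80 (psmb12 2.90), p53 genes at 0.89 (plk2b 2.97, ccng2 2.82) and JAK-STAT3 genes at 0.62 (socs1b 2.94). Cytokines were at 0.51, led by the interferon-induced chemokine cxcl11.1 (4.06 (3.19 to 5.09)) and ccl34b.8 (3.0). Cell cycle genes were at 0.94 (cdk1 2.02, rrm2 1.92), and the stress response at 0.39 (ddit4 1.99). Repair genes had a median of −0.22, with 9 members higher, spp1 (5.40 (4.01 to 7.29)) and arg2 (3.8) most, and 13 lower, chia.1 (no UMI against 149) and mrc1a (−1.47) most. Fgf genes were at −0.67 (spry1 −1.49) but at −0.10 when cells were thinned to a fixed depth. Of the 8 highest genes, jac3 (5.92), jac2 (4.53) and jac9 (4.23) were lectins, and prss59.1 (4.23) and amy2a (4.21) came from the pancreas. The 8 lowest were the chitinase genes chia.1 and chia.2 (−5.84), the gut markers fabp1b.1 (−5.34) and fabp2 (−4.42), kif9 (−3.29), entpd2a.2 (−4.15), pax7b (−3.47) and ptgdsb.1 (−3.38). All genes together had a median of 0.11.

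Against MTZ+1h, neomycin+1h macrophages had lower cell cycle genes, with some heat shock genes lower and some JAK-STAT3 and repair genes higher. Cell cycle genes were at −0.75 (−0.88 to −0.67) with 21 of 38 members lower, cdt1 (−2.98) and mcm5 (−2.41) most. Heat shock genes were at −0.57 (−0.70 to −0.53) with 10 of 20 lower and none higher, hsp70.3 (−3.91 (−4.71 to −3.2)) and hsp70.2 (−3.0) most. JAK-STAT3 genes were at 0.48 (0.38 to 0.55) with 10 of 22 higher, osmr (1.71) and socs3b (1.63) most. Repair genes were at 0.28 (mmp9 2.47, arg2 1.96), cytokines at 0.30 (cxcl8b.1 1.36), interferon genes at 0.35 (mxe 2.28) and antigen presentation at 0.31 (mhc2a 1.06). The stress response was at −0.23 (ddit4 −1.95) and immediate early genes at −0.03. Among the highest genes were the intestinal genes chia.2 (8.59 (6.74 to 11.64)), slc15a1a (6.58 (4.07 to 11.90)), fabp2 (6.40), fabp1b.1 (5.83) and apoa4b.2 (4.68), with zanl (6.29 (4.41 to 9.34)) and cd36 (6.14 (4.26 to 9.20)). Among the 8 lowest were the kidney genes slc22a6l (−6.92), slc13a3 (−5.30), slc20a1a (−5.42), slc5a12 (−3.95) and lrp2a (−3.46), with slc2a11l (−6.91 (−12.23 to −4.41)), hsp70.3 and cdca7a (−3.78). The median over all genes was −0.11.

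Several of these gene groups differed in other classes as well. In neomycin+0h the immediate early list was at 1.96 in neutrophils, 1.71 in lymphoid cells and 1.27 in metaphocytes of the macrophage sort. It was at 1.80 in fibroblasts and 2.29 in epidermis of the lateral line sort. Interferon genes in neutrophils were at −1.73, −1.97 and −1.63 in MTZ-1h, MTZ+0h and MTZ+1h and at −1.09 in neomycin+1h, against −0.33 in neomycin+0h. Neutrophils lay in different clusters, however: clusters 14 and 33 held 367 and 122 of 1536 untreated neutrophils and 330 and 46 of 1056 in neomycin+0h, but at most 10 and 19 in any other library. Within cluster 0 the interferon list was at −1.28, −1.22 and −0.82 in MTZ-1h, MTZ+0h and MTZ+1h, −0.50 in neomycin+1h and −0.07 in neomycin+0h. In metaphocytes the interferon list was at −1.40, −1.06 and −0.81 in MTZ-1h, MTZ+0h and MTZ+1h, −0.55 in neomycin+1h and 0.10 in neomycin+0h. Untreated and neomycin+0h thus stood apart from the other 4 libraries in interferon genes of several classes, and with 1 library per group treatment was not separable from library. Heat shock genes were far higher in erythroid cells of the MTZ libraries, at 4.75, 4.75 and 3.85 in the macrophage sort and 4.38, 3.67 and 3.57 in the lateral line sort. These cells did not lie in the same clusters as untreated ones: cluster 31 of the macrophage sort (63, 35 and 133 cells) and cluster 30 of the lateral line sort (93, 80 and 117 cells) held only MTZ cells. In the clusters shared with untreated cells the list, with 3 to 8 measured genes, was at 2.29, −0.39 and 1.95 in the macrophage sort and 4.15, −0.32 and 4.07 in the lateral line sort. In epidermis of the lateral line sort heat shock genes were at 0.97, 1.01 and 0.81, and at 0.86 in neomycin+1h. In MTZ-1h, MTZ+0h and MTZ+1h the list was at −0.41, −0.43 and 0.18 in neutrophils, −0.42, −0.26 and 0.53 in metaphocytes and −0.24, −0.23 and −0.03 in lymphoid cells.

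**Figure D3:**
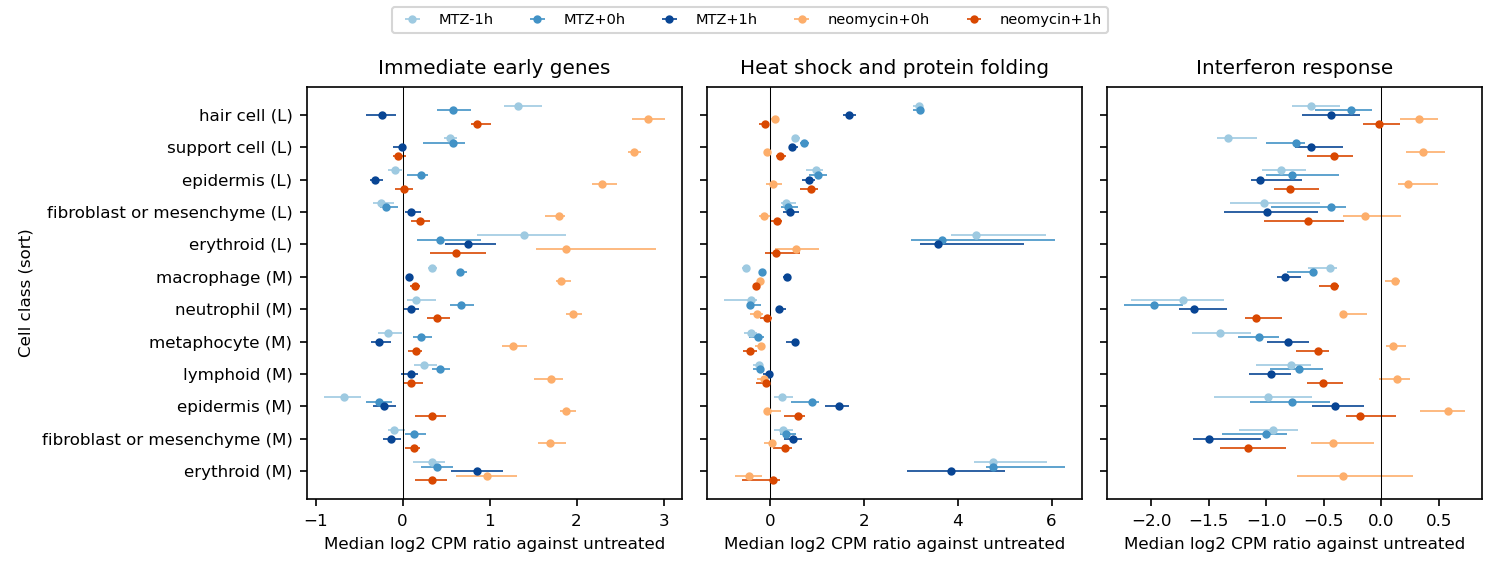
Median log2 CPM ratios of 3 gene lists (95% counting intervals) in each cell class of both sorts, per treated library against untreated. In erythroid cells of the macrophage sort heat shock genes lay at 4.75 in MTZ-1h, −0.46 in neomycin+0h and 0.05 in neomycin+1h.

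The macrophage sort also held a few cells with hair cell transcripts. They fell in cluster 28, which held 0.0455% (0.0124 to 0.117%, 4 cells) of the untreated macrophage sort. The share of cluster 28 in the macrophage sort was 0.818% (0.634 to 1.04%) in MTZ-1h, 0.564% in MTZ+0h, 0.355% in MTZ+1h, 0.442% in neomycin+0h and 0.723% in neomycin+1h. The 4 untreated cells had 170870 CPM of hair cell markers against 5904 to 16376 in the treated cells of the cluster, so unlike cells were counted. To count cells with both sets of transcripts at 1 depth, each cell was thinned to 2000 UMIs. Of untreated cells, 2 of 7768 (0.0257%, 0.00312 to 0.0930%) held at least 5 UMIs of hair cell markers and 25% or more of the macrophage marker level. After MTZ there were 27 of 7504 (0.360%, 0.237 to 0.523%) in MTZ-1h, 20 of 8332 (0.240%) in MTZ+0h and 12 of 6817 (0.176%) in MTZ+1h. Neomycin+0h had 11 of 7026 (0.157%, 0.0782 to 0.280%) and neomycin+1h had 27 of 7300 (0.370%, 0.244 to 0.538%). With a lower limit of 5 macrophage marker UMIs the untreated library had 17 cells (0.219%), and the treated ones 32, 24, 17, 18 and 33 in the same order, so the contrast depended on the limit.

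**Figure D4:**
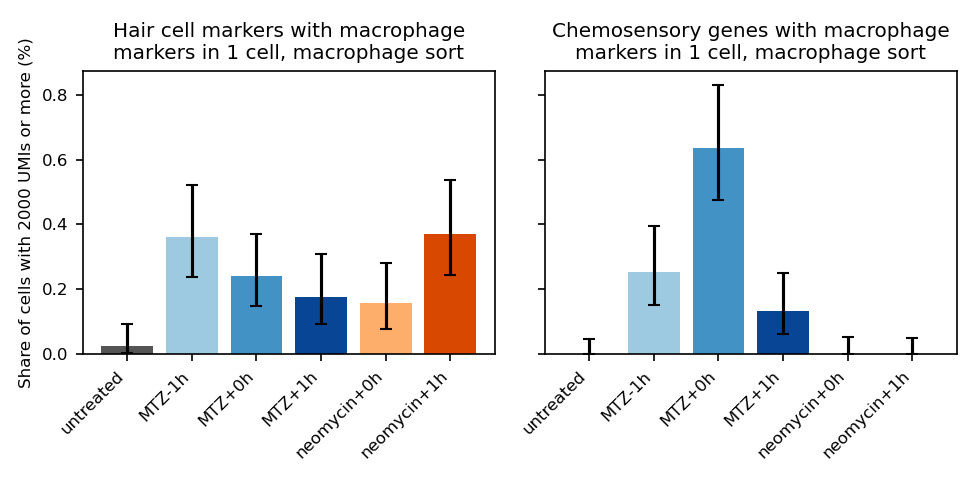
Share of macrophage sort cells (percent, exact 95% intervals) that held both hair cell and macrophage transcripts after thinning to 2000 UMIs, per library. The untreated library lay at 0.0257% and the treated ones between 0.157% and 0.370%.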

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

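Of the tests below, 3 were chosen only after the result was seen: heat reaching every cell, and free RNA and doublets for cells with both sets of transcripts. The same holds for the thinned mCherry shares and for erythroid clusters other than cluster 30. In the macrophage sort, transcripts of mCherry, which both the hair cell and the lateral line transgenes carry, were counted from gene entries that no comparison used. Untreated cells with an mCherry UMI were 0.171% (0.0956 to 0.282%, 15 of 8783). The share was above that in MTZ+1h, 0.709% (0.533 to 0.925%, 54 of 7612), in neomycin+0h, 0.429% (0.296 to 0.603%, 33 of 7685), and in neomycin+1h, 0.576% (0.423 to 0.765%, 47 of 8162). MTZ+0h, at 0.355% (0.246 to 0.496%), overlapped the untreated interval. The transcripts were mostly outside macrophages: 4 macrophages had such a UMI in MTZ+1h, and none of the 2975 untreated did. Thinned to 2000 UMIs, the shares were 0.0772% (0.0284 to 0.168%) untreated, 0.308% (0.191 to 0.471%) in MTZ+1h, 0.356% (0.233 to 0.521%) in neomycin+1h and 0.213% (0.120 to 0.352%) in neomycin+0h, the last overlapping. No row for mCherry was found in the MTZ-1h library.

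Immediate early genes such as nr4a3 were higher in neomycin+0h. A stimulus during handling or dissociation might reach every cell, and the lowest median over 5 other classes, in fibroblasts, was 1.70 (1.55 to 1.88), the highest 2.29. Outside those 5, metaphocytes were at 1.27 and erythroid cells of the macrophage sort at 0.97 (0.62 to 1.32). A shift of cells between support cell clusters was excluded, since the lowest median within 4 clusters was 2.86 (2.79 to 3.43). Handling stays open, and so does a response of the whole larva to neomycin, which was not tested.

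Heat shock genes such as hsp70.3 were higher in hair cells and erythroid cells of the MTZ libraries. Heat or handling that reached every cell stays open. The list was at −0.19 (−0.25 to −0.17) in MTZ+0h macrophages, which came from another library than the hair cells. These macrophages left out cluster 21, which held 4 untreated and 117, 198 and 78 MTZ cells. It scored as macrophage, with 28 macrophage markers detected against 34 to 44 in named macrophage clusters. Its leading genes were gng13a, calb2a and gnb3a, then hsp70l. Of these, gng13a and gnb3a are counted below among chemosensory genes, and calb2a was in the hair cell marker list. Cluster 24 of the lateral line sort, which scored as epidermis, also had gng13a, calb2a and gnb3a among its leading genes. What the cells of cluster 21 were stayed unclear. MTZ+0h neutrophils were at −0.43, metaphocytes at −0.26 and lymphoid cells at −0.23. In the lateral line library support cells were at 0.71, fibroblasts at 0.38 (0.23 to 0.59) and epidermis at 1.01 (0.82 to 1.2). Free RNA from hair cells was excluded for erythroid cells: cluster 30 held 0.00864 (0.00818 to 0.00914) times as many hair cell marker UMIs per hsp70 UMI as the hair cells did, and the other 3 erythroid clusters of both sorts at most 0.168 (0.147 to 0.193) times as many. A response to toxic MTZ products may be the reason in hair cells, but the labels name no nitroreductase in erythroid or epidermal cells, and a difference between library batches was not tested.

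After treatment cluster 28 held more cells, unlike its 4 untreated ones in hair cell marker CPM (5904 to 16376 against 170870), and so did the group with both hair cell and macrophage transcripts at the higher macrophage limit, though MTZ+1h matched untreated in number at the lower one (17 cells each). Pooled over libraries, the median depth was 0.895 (0.781 to 0.999) times that of macrophages in 245 cells of the cluster. It was 0.764 (0.628 to 1.02) times in 97 cells with both sets. This argues against doublets of 2 whole cells as the main source. Such doublets were not excluded for part of the cells, since called doublets had been removed before and the median pools unlike libraries. Cluster 28 had a median of 5533 UMIs in MTZ+1h, against 15459 in macrophages, and 11650 against 12012 in MTZ+0h. Free RNA spread evenly was excluded for cells with both sets. Of the treated libraries neomycin+0h had the fewest, 11 (5.49 to 19.7), where such a spread gives 0.00437. Free RNA spread unevenly over the droplets was not tested. In macrophages outside the cluster hair cell marker CPM was lower after treatment (15.8 untreated, 6.88 to 9.75 treated). The fold, treated over untreated, ran from 0.418 (0.332 to 0.527) to 0.855 times that in neutrophils. No treated library thus had a greater fold in macrophages than in neutrophils, and free RNA there stayed undecided. Macrophages that took up hair cell remains could give such cells, and so could a macrophage sorted while stuck to a hair cell fragment, which was not tested.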

How the results depend on the processing

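The wider set of clusters was chosen only after the data were seen, and the gate on marker UMIs was redefined once after a first result. The other alternatives were chosen before. Of 84 alternative values for the hair cell and macrophage shares, 37 stayed within the counting interval and 47 did not. Of 152 alternative values for the 19 leading list medians, 90 stayed within their interval, 61 lay outside it with the same sign and 1 reversed. Of 464 values for 58 other lists, the numbers were 280, 179 and 5. Only lists with at least 8 measured members and a median of at least 0.585 above or below 0 were counted. Smaller medians, less far from a change of sign, are not covered by these numbers. Immediate early genes in neomycin+0h and heat shock genes in MTZ hair cells kept their sign in each alternative run for them. The 6 reversals of list medians were 5 of support cell cytokine medians and 1 of a calcium list. No paired analysis was possible because each group had 1 library, and with no replicates none could be left out.

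With a stricter cell filter the hair cell share was 12.4% in MTZ-1h and 6.70% in MTZ+0h, and the macrophage share was 34.9% in untreated, 68.2% in MTZ-1h, 52.2% in MTZ+0h, 42.3% in MTZ+1h, 41.1% in neomycin+0h and 46.2% in neomycin+1h. Macrophage medians were: cell cycle −1.63 (MTZ-1h), immediate early 1.99 (neomycin+0h). In support cells, medians were: immediate early 2.75 (neomycin+0h) and 2.52 (neomycin+0h over MTZ+0h), cytokine 0.08 (neomycin+1h) and −0.11 (neomycin+1h over MTZ+1h), Notch −1.43 (neomycin+1h). Hair cell medians were: heat shock 3.0 (MTZ-1h) and 1.48 (MTZ+1h), immediate early 3.12 (neomycin+0h), JAK-STAT3 1.39 (neomycin+1h). With a looser cell filter the hair cell share was 18% in untreated and 16.6% in MTZ-1h, and the macrophage share was 27.9% in untreated, 65.0% in MTZ-1h, 44.0% in MTZ+0h, 37.6% in neomycin+0h and 39.3% in neomycin+1h. With called doublets kept the hair cell share was 15.8% in MTZ-1h, and the macrophage share was 18.7% in untreated, 62.8% in MTZ-1h, 42.6% in MTZ+0h, 35% in MTZ+1h, 26.5% in neomycin+0h and 37.9% in neomycin+1h. Macrophage medians were: cell cycle −1.75 (MTZ-1h) and −1.64 (neomycin+1h), immediate early 0.91 (neomycin+0h over MTZ+0h). Support cell medians were: immediate early 2.43 (neomycin+0h). Hair cell medians were: heat shock 2.94 (MTZ-1h), JAK-STAT3 0.94 (neomycin+1h). At Leiden resolution 0.5 the macrophage share was 28.9% in untreated, 48.1% in MTZ+0h, 39.0% in MTZ+1h, 35.0% in neomycin+0h and 43.2% in neomycin+1h. At Leiden resolution 2 the macrophage share was 17.9% in untreated, 64.2% in MTZ-1h, 43.3% in MTZ+0h, 34.4% in MTZ+1h, 27.5% in neomycin+0h and 39.6% in neomycin+1h. Macrophage medians were: cell cycle −1.71 (MTZ-1h), −1.18 (MTZ+0h) and −1.67 (neomycin+1h), interferon −0.99 (MTZ+1h), immediate early 1.76 (neomycin+0h). In support cells, medians were: calcium 0.19 (MTZ-1h), Notch −1.04 (neomycin+1h), immediate early 2.35 (neomycin+0h over MTZ+0h), cytokine −0.58 (neomycin+1h over MTZ+1h). With a gate on marker UMIs the hair cell share was 20.5% in untreated, 6.46% in MTZ+0h and 2.51% in MTZ+1h, and the macrophage share was 30.5% in untreated, 51.7% in MTZ-1h, 30.6% in MTZ+0h, 28.2% in MTZ+1h and 36.3% in neomycin+1h. By that gate the share of macrophages in MTZ+0h was level with untreated and in MTZ+1h below it, where the clusters put both above. In the wider set of clusters the macrophage share was 38.3% in untreated, 68.5% in MTZ-1h, 48.5% in MTZ+0h, 39% in MTZ+1h, 45.5% in neomycin+0h and 43.3% in neomycin+1h. Macrophage medians were: cell cycle −1.41 (MTZ-1h), immediate early 1.74 (neomycin+0h) and 1.14 (neomycin+0h over MTZ+0h). Support cell medians were: cytokine 0.10 (MTZ-1h), 0.22 (neomycin+1h) and 0.22 (neomycin+1h over MTZ+1h), Notch −1.0 (neomycin+1h), immediate early 1.89 (neomycin+0h over MTZ+0h). After median-of-ratios scaling macrophage medians were: cell cycle −1.30 (neomycin+1h) and −0.64 (neomycin+1h over MTZ+1h), immediate early 0.96 (neomycin+0h over MTZ+0h). In support cells, medians were: immediate early 2.91 (neomycin+0h) and 2.5 (neomycin+0h over MTZ+0h), cytokine −0.82 (neomycin+1h over MTZ+1h). Hair cell medians were: heat shock 3.24 (MTZ-1h) and 1.51 (MTZ+1h), immediate early 2.61 (neomycin+0h), JAK-STAT3 0.90 (neomycin+1h). With equal weight per cell macrophage medians were: cell cycle −0.75 (MTZ+0h) and −1.32 (neomycin+1h), immediate early 1.96 (neomycin+0h) and 1.22 (neomycin+0h over MTZ+0h). Support cell medians were: immediate early 2.75 (neomycin+0h), Notch −1.36 (neomycin+1h), cytokine −1.15 (neomycin+1h over MTZ+1h). Hair cell medians were: heat shock 3.35 (MTZ-1h) and 2.37 (MTZ+1h). With each cell thinned to a fixed depth macrophage medians were: cell cycle −1.59 (MTZ-1h), −0.69 (MTZ+0h) and −0.67 (neomycin+1h over MTZ+1h), immediate early 1.2 (neomycin+0h over MTZ+0h). In support cells, medians were: JAK-STAT3 1.45 (MTZ+0h), Fgf −0.54 (MTZ+1h), immediate early 2.28 (neomycin+0h over MTZ+0h), cytokine −1.06 (neomycin+1h over MTZ+1h). Hair cell medians were: heat shock 3.35 (MTZ-1h) and 2.31 (MTZ+1h). With genes of at least 30 UMIs support cell medians were: cytokine 0.19 (MTZ+0h) and −0.66 (neomycin+1h over MTZ+1h). Hair cell medians were: heat shock 3.01 (MTZ-1h), JAK-STAT3 0.72 (neomycin+1h).

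Values that reversed were the support cell medians for cytokines in MTZ-1h (0.10, wider set), MTZ+0h (0.19, at least 30 UMIs), neomycin+1h (0.083, stricter filter, and 0.22, wider set) and neomycin+1h over MTZ+1h (0.22, wider set), and for calcium transport in MTZ-1h (0.19, resolution 2). The support cell interferon median in MTZ+1h, −0.61 under the settings used, was −0.84 with the stricter filter, −0.84 with doublets kept and −0.77 with genes of at least 30 UMIs. The cause was not tested for any of these values. Median-of-ratios scaling took the median of all genes from −0.28 to −0.03 in support cells of neomycin+0h and from 0.12 to −0.15 in hair cells of neomycin+1h. Depth limited genes with few UMIs in hair cells of MTZ+1h, of which 221 were found.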

Other observations

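All counts of chemosensory cells below were chosen after the data were seen. Cells with at least 5 UMIs of gng13a, gnb3a, trpm5, gna14a and kcnk17, genes of taste-like signalling chosen after their values were seen, made up 1.58% (118 of 7485) of the untreated lateral line sort at 2000 UMIs. They made up 2.94% in neomycin+1h and 0.171% in MTZ+1h. Cluster 26, with gna14a and kcnk17 among its leading genes, had a median of 1848 UMIs, below that limit. It held 25 untreated cells, 102, 140 and 25 in MTZ-1h, MTZ+0h and MTZ+1h, and 18 and 67 after neomycin. Cluster 24 had gng13a and gnb3a among its leading genes. It held 114 untreated cells, 5, 3 and 9 in the MTZ libraries in that order, and 78 and 214 after neomycin.

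In the macrophage sort such transcripts appeared in cells that also held macrophage transcripts. No untreated cell had both, which allows a share of up to 0.0475%. MTZ-1h had 19 such cells (0.253%), MTZ+0h had 53 (0.636%) and MTZ+1h had 9 (0.132%), and the neomycin libraries had none. Cluster 21 of the macrophage sort, with gng13a and gnb3a among its leading genes, held 4 untreated cells. It held 117, 198 and 78 cells of the MTZ libraries in the same order, and 3 and 7 after neomycin. No cause was tested.

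With cells thinned to 2000 UMIs, EGFP transcripts were found in 34.4% of untreated macrophages and in 30.9%, 34.5%, 22.3% and 30% in MTZ+0h, MTZ+1h, neomycin+0h and neomycin+1h. They were in 6.98% of untreated neutrophils and 62.7% of untreated metaphocytes, and how much of this was background RNA was not measured.

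Pigment cells were 2.95% of the untreated macrophage sort, 0.134% in MTZ-1h and 6.07% in MTZ+1h. Ionocytes were 3.14% of the untreated macrophage sort and 0.638% or less in each treated library.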
